A study of Arabidopsis thaliana with 40 samples.

How the data were processed

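The series holds 40 samples of Arabidopsis thaliana shoots (the design text calls the material leaves) from plants 4 weeks old. They form 10 groups, WT, 2cysprx, cyp20-3, oastlB and serat2;1, each in normal light and after 6 h of high light, with 4 biological replicates per group according to the labels. RNA was extracted with a peqGOLD kit and biotin-labelled cRNA was hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The array type and the grouping of probes into probe sets are not given in the sources used here.

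The authors deposited 1 table of log2 values, made by RMA per the submitters' processing notes, which background-corrects, quantile-normalizes and summarizes probe intensities on the log2 scale. Its version is not given in the sources used here. All 40 columns matched 1 sample each by its labels. The table held 27826 probe sets, each named by 1 locus code, with 0 control probe sets, so every one was tested and no filter on dim genes was applied. Symbols came from a reference table of the TAIR10.1 assembly, which held 27241 of the loci, and the other 585 keep their code. No coordinates are given, because the build behind the probe sets is not stated. The values hold no detection calls, so signal over background is unknown and the number of arrays sets the precision. Pearson's r between arrays across genes lay between 0.973 and 0.993.

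All arrays were fitted with limma 3.58.1 in R 4.3.3 as 1 model with a mean per group (residual degrees of freedom 30, prior 3.90), so that all groups share an estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes within each of 17 contrasts: high against normal light in each genotype, each mutant against WT in each light, and the difference of each mutant's light response from that of WT. A gene was called at an adjusted p under 0.05. Gene lists were tested with camera in the same model at a preset correlation of 0.01, adjusted over 23 lists within a contrast. An estimated correlation and fry, which tests whether a list's genes move on balance in one direction, were run beside it.

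The lists hold 326 genes. They are sulfate assimilation and cysteine synthesis, sulfur starvation markers, antioxidant enzymes, the plastid thioredoxin system, high light and reactive oxygen markers, heat shock proteins and chaperones, flavonoid and anthocyanin synthesis, light harvesting proteins, chlorophyll synthesis, carotenoid synthesis and the xanthophyll cycle, the Calvin-Benson cycle, jasmonate synthesis and signalling, salicylate and immune response, glucosinolate synthesis, abscisic acid and dehydration response, the circadian clock, dark and starvation inducible genes, shade and elongation markers, cyclophilins, and 4 marker lists of root, floral, guard and myrosin, and dividing cells. In the light responses of WT, 2cysprx, cyp20-3, oastlB and serat2;1, camera called 11, 12, 12, 15 and 15 lists, of which 6, 6, 8, 12 and 7 held with an estimated correlation. For the mutants in the same order it called 7, 0, 7 and 8 lists in NL (1, 0, 0 and 1 held), 5, 9, 4 and 7 in HL (2, 6, 2 and 0), and 8, 5, 8 and 8 for the difference in light response (1, 0, 2 and 0). These counts include lists that hold the line's targeted gene. Not every called list is described.

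The groups, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. By that rule a gene is named if it was called and its 4 against 4 values do not overlap (for differences in light response, if called). It takes the 10 largest rises and falls in the WT light response, 5 of each per mutant and light and 3 of each per difference in response. It adds the 2 largest rises and falls per list in the WT light response. In the other contrasts it adds the 2 largest changes in lists that camera called or that hold at least 3 called members, and called members of the sulfate list and targeted genes. Of the genes it gives, those printed are a selection.

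A clock index was set up later, as the median of 6 morning genes (LNK1, LNK2, LNK3, RVE1, RVE7, CDF1) minus that of 4 evening genes (BOA, COR27, AT4G33980, GRP7), none of them in the clock list. RVE7 is the gene also printed as EPR1. The shifts of listed clock genes were known by then. So were the values of AT4G33980 in the WT light response and of EPR1 in the oastlB difference in response, which hold the same WT NL arrays. Correlations between mutants' differences from WT were set beside 100 simulated draws of unchanged groups with a shared WT group, also simulated. They were repeated with the WT arrays split into 2 and 2.

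The alternatives were an intensity trend in the prior variance, a replicate block, only the arrays of the compared groups, only the brighter genes (mean level at or above the median gene), quantile or cyclic loess normalization of the deposited values, array weights, leaving out each array of the compared groups in turn, and leaving out genes within 1000 locus numbers of a targeted locus. After the data were seen, camera was also run on lists without the targeted genes of the line compared, calls shared by 2 mutants were counted with WT arrays split, and a fit was added without the arrays that stood apart. The latter were the arrays whose root mean square deviation from their group mean exceeded 0.25 (2cysprx NL replicate 2, WT NL replicate 1, oastlB HL replicates 2 and 4) and 2cysprx HL replicate 2 for its 2CPA level. Averaging several probe sets per gene was not run, since each gene had 1.

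The procedure was tested on simulated data for all 27826 genes. Of genes shifted by 0.5, 1 and 2 log2 it recovered 29.9%, 92.5% and 98.5% for cyp20-3 against WT in NL, 46.3%, 89.6% and 100% for the WT light response, and 8.96%, 74.6% and 98.5% for the 2cysprx difference in response. Of its calls 8.12%, 5.99% and 5.47% were false. With no change simulated it called 1 gene in 1 of the 17 contrasts and 0 in the others.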

Results

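Transcript levels were measured on 40 Affymetrix arrays in shoots of Arabidopsis thaliana, with 1 array for each of 4 biological replicates in 10 groups. Wild type (WT) and the lines 2cysprx, cyp20-3, oastlB and serat2;1 were grown in soil for 4 weeks in short days of 8 h light and 16 h darkness. Plants either stayed at 80 µmol quanta m-2 s-1 (normal light, NL) or received 800 µmol quanta m-2 s-1 for 6 h (high light, HL). The lines carry defects in parts of a chloroplast module of 2-Cys peroxiredoxin, which reduces peroxides, the cyclophilin CYP20-3, and the enzymes of cysteine synthesis, O-acetylserine(thiol)lyase and serine acetyltransferase. The comparisons ask what each line changes in NL and in HL, and whether its response to high light differs from that of WT. Values were log2 intensities of 27826 probe sets, each named by 1 locus. Differences are given as log2 difference ± standard error from the limma fit, and levels as log2 mean ± SD (n = 4 arrays). The number of arrays limits precision, no 2 arrays held identical values, and no coordinates are given.

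The transcripts of the targeted genes were much lower in 3 of the 4 lines. The 2-Cys peroxiredoxin gene 2CPA (AT3G11630) stood at 5.31 ± 0.24 in 2cysprx and 10.70 ± 0.19 in WT in NL (-5.39 ± 0.40, adjusted p = 3.0e-11), and at 6.31 ± 1.81 and 10.96 ± 0.13 in HL (-4.65 ± 0.40, adjusted p = 1.9e-09). The second gene, 2CPB (AT5G06290), was at 6.82 ± 0.19 against 9.20 ± 0.15 in NL (-2.38 ± 0.15, adjusted p = 2.0e-12) and at 6.96 ± 0.54 against 9.29 ± 0.24 in HL (-2.33 ± 0.15, adjusted p = 3.7e-12). CYP20-3 (AT3G62030) was at 6.47 ± 0.22 in cyp20-3 against 10.57 ± 0.10 in NL (-4.10 ± 0.11, adjusted p = 3.4e-24) and 6.47 ± 0.37 against 10.51 ± 0.10 in HL (-4.04 ± 0.11, adjusted p = 5.7e-24). OASB (AT2G43750), the plastid O-acetylserine(thiol)lyase, was at 4.68 ± 0.08 in oastlB against 9.19 ± 0.10 in NL (-4.51 ± 0.14, adjusted p = 7.2e-23) and 4.25 ± 0.56 against 9.08 ± 0.07 in HL (-4.83 ± 0.14, adjusted p = 7.8e-24). SERAT2;1 (AT1G55920), the plastid serine acetyltransferase, was not lower in the arrays labelled serat2;1, at 6.38 ± 0.20 against 6.36 ± 0.22 in NL (0.02 ± 0.14, adjusted p = 0.968) and 6.81 ± 0.16 against 6.34 ± 0.08 in HL (0.47 ± 0.14, adjusted p = 0.101). The position of the probes relative to the mutated site is not given in the sources used here, so this transcript neither bears out nor contradicts that label, and serat2;1 stands below for the arrays so labelled. On 1 array, 2cysprx HL replicate 2, 2CPA read 9.0, while the other 3 arrays of the group read 5.13 to 5.78. 2CPB was also highest on that array, at 7.67 against 6.41 to 7.06.

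**Figure D1:**
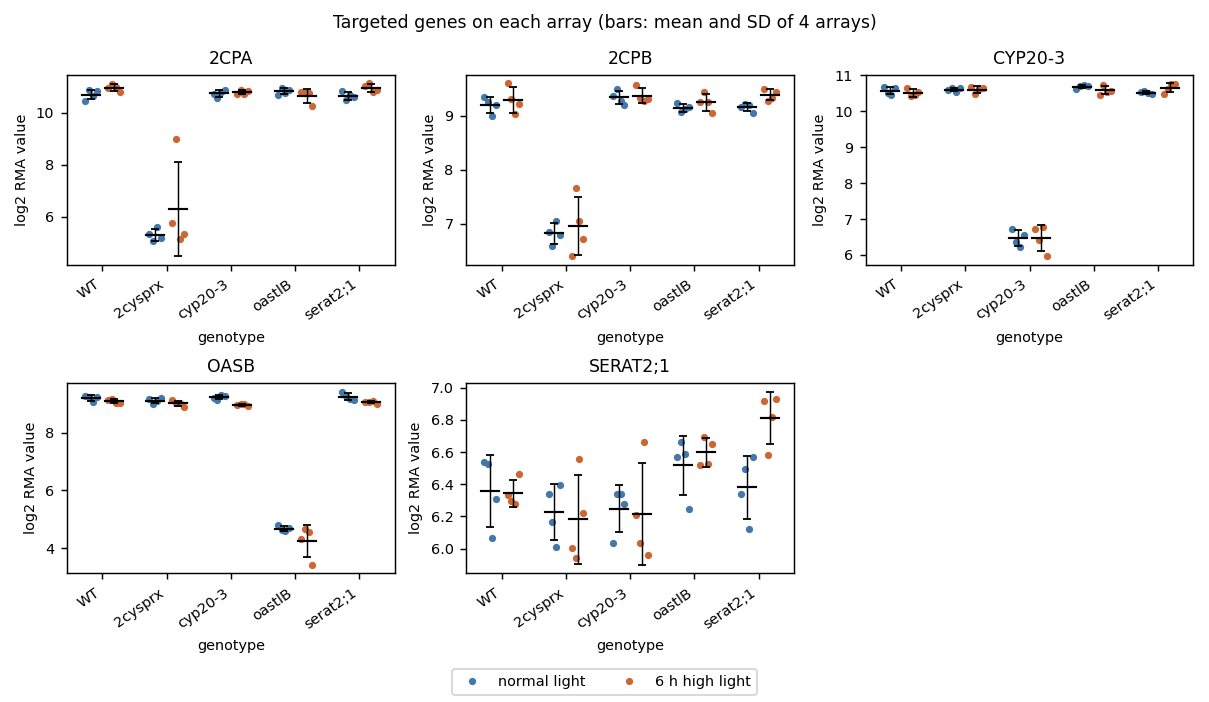
Log2 level of the 5 targeted genes on each of the 40 arrays (points) by genotype and light, with the group mean and SD (n = 4). 2CPA, 2CPB, CYP20-3 and OASB are lower in the line named for them, with 2CPA at 9.0 on 1 array of 2cysprx in HL, and SERAT2;1 overlaps between serat2;1 and WT in NL.

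The light comparisons held most of the called differences. In WT, 5519 genes were called at an adjusted p under 0.05, of which 468 changed at least 2-fold, against 2380 in 2cysprx, 4959 in cyp20-3, 4495 in oastlB and 3184 in serat2;1. Between mutants and WT, the counts in NL ranged from 13 genes in cyp20-3 to 2819 in 2cysprx, and in HL from 238 in oastlB to 622 in cyp20-3.

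**Figure D2:**
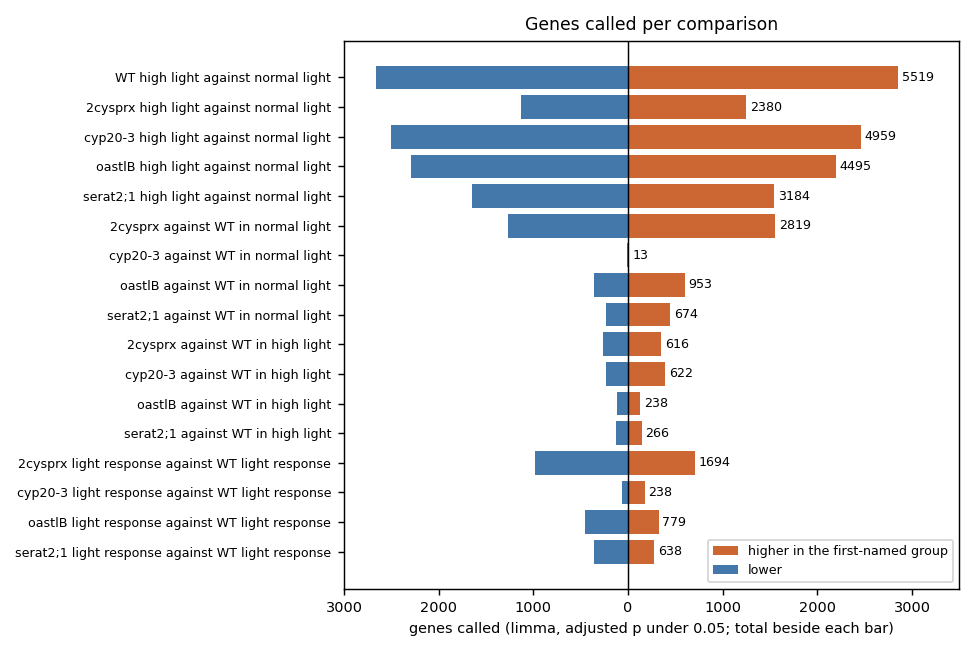
Number of genes called higher and lower (adjusted p under 0.05, limma) in each of the 17 comparisons. The WT light response has the most calls, 2854 higher and 2665 lower, and cyp20-3 against WT in NL the fewest, 6 and 7.

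In WT, 2854 genes rose and 2665 fell from NL to HL. The strongest rises were those of AT1G07400 (3.88 ± 0.56, adjusted p = 3.1e-06), a small heat shock protein gene, of GPT2 (AT1G61800, 3.72 ± 0.26, adjusted p = 1.8e-12), which encodes a plastid glucose-6-phosphate translocator, and of HSFA2 (AT2G26150, 3.69 ± 0.43, adjusted p = 6.7e-08), a heat shock transcription factor. GPT2 went from 4.88 ± 0.34 to 8.60 ± 0.14, a 13.1-fold rise. The lipid transfer protein genes LTP3 (AT5G59320, 3.60 ± 0.37) and LTP4 (AT5G59310, 3.59 ± 0.43), the cellulose synthase-like gene CSLA01 (AT4G16590, 3.56 ± 0.37), the chaperone genes HSP70 (AT3G12580, 3.45 ± 0.34) and HSP90.1 (AT5G52640, 3.09 ± 0.39), AT3G28270 (3.31 ± 0.24) and AT3G24420 (3.18 ± 0.14) completed the 10 largest. The deepest falls were those of AT2G33830 (-2.38 ± 0.17, adjusted p = 3.5e-12), BT2 (AT3G48360, -2.20 ± 0.29), AT1G15125 (-2.19 ± 0.30), AT4G33980 (-2.00 ± 0.12), AT3G28310 (-2.00 ± 0.23), AT3G15630 (-1.94 ± 0.21), TPS11 (AT2G18700, -1.94 ± 0.24), of the trehalose phosphate synthase family, DYL1 (AT1G28330, -1.91 ± 0.13), SEN5 (AT3G15450, -1.87 ± 0.23) and PR4 (AT3G04720, -1.85 ± 0.22), a hevein-like gene.

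Antioxidant and photosynthetic carbon genes were called higher as lists in HL. In WT 9 of 28 antioxidant enzymes rose and 3 fell (10 and 4 adjusted over the list alone), among them DHAR2 (AT1G75270, 1.4 ± 0.17), a dehydroascorbate reductase, and the catalase CAT2 (AT4G35090, 1.13 ± 0.13), while CAT1 (AT1G20630, -0.39 ± 0.09) fell. The set test camera called the list higher (adjusted p = 6.9e-04), and here and below such a call also held with an estimated correlation unless that p is given. Of the Calvin-Benson cycle genes, 6 of 10 rose and 0 fell (6 and 0 adjusted over the list alone), led by the rubisco small subunits RBCS1B (AT5G38430, 1.29 ± 0.14) and RBCS2B (AT5G38420, 1.07 ± 0.09). Camera called the Calvin-Benson list higher (adjusted p = 2.0e-05). Likewise 5 of 8 shade and elongation markers rose and 1 fell (5 and 1 adjusted over the list alone), with the transcription factor genes PIL1 (AT2G46970, 2.26 ± 0.28) and HFR1 (AT1G02340, 1.95 ± 0.26). Camera called the shade list higher (adjusted p = 3.0e-05). Of the cyclophilins 5 of 13 rose and 1 fell (5 and 1 adjusted over the list alone), with ROC2 (AT3G56070, 0.95 ± 0.17) and ROC1 (AT4G38740, 0.57 ± 0.09) up and CYP38 (AT3G01480, -0.50 ± 0.07) down. Camera called the cyclophilin list higher (adjusted p = 0.01). In contrast 0 of 11 dark and starvation inducible genes rose and 7 fell (0 and 7 adjusted over the list alone), TPS11 and SEN5 leading. Camera called the dark inducible list lower (adjusted p = 1.1e-05). In the circadian clock list 2 of 12 rose and 7 fell (3 and 8 adjusted over the list alone), the morning genes PRR9 (AT2G46790, 2.50 ± 0.20) and CCA1 (AT2G46830, 1.03 ± 0.15) rising and the evening genes FKF1 (AT1G68050, -1.41 ± 0.11) and ELF4 (AT2G40080, -1.24 ± 0.16) falling. Camera called the clock list lower (adjusted p = 2.0e-04). For 10 further clock-phased genes, the median of 6 morning genes minus that of 4 evening genes moved by 1.14 log2 in WT between the lights, 9 of the 10 toward an earlier hour. Of these, AT4G33980 was known to fall before the index was set up. Harvest hours are not given and were not separated from light.

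Heat shock, flavonoid and jasmonate genes were called higher in WT by camera with its preset correlation, but these calls were lost with an estimated one. Here 10 of 20 heat shock proteins and chaperones rose and 0 fell (13 and 1 adjusted over the list alone), HSFA2 and HSP70 with the largest rises. Camera called the heat shock list higher (adjusted p = 1.3e-07, and adjusted p = 0.0911 with an estimated correlation). Of the flavonoid and anthocyanin genes 9 of 25 rose and 0 fell (12 and 0 adjusted over the list alone), with the anthocyanin regulator PAP1 (AT1G56650, 1.17 ± 0.21) and the glutathione transferase gene GSTF12 (AT5G17220, 0.99 ± 0.27). Camera called the flavonoid list higher (adjusted p = 1.1e-05, and adjusted p = 0.132 with an estimated correlation). Of the jasmonate genes 8 of 24 rose and 1 fell (13 and 1 adjusted over the list alone), VSP2 (AT5G24770, 1.05 ± 0.28) up and JAZ3 (AT3G17860, -0.51 ± 0.12) down. Camera called the jasmonate list higher (adjusted p = 6.1e-04, 0.294 with an estimated correlation and 0.056 among the brighter genes). In the same way 4 of 17 high light and reactive oxygen markers rose and 0 fell (4 and 0 adjusted over the list alone). Camera called the reactive oxygen list higher (adjusted p = 0.00526, 0.294 with an estimated correlation and 0.0995 among the brighter genes). Of the salicylate and immune genes 0 of 19 rose and 10 fell (0 and 10 adjusted over the list alone), including the regulators SARD1 (AT1G73805, -1.55 ± 0.17) and CBP60G (AT5G26920, -0.88 ± 0.18). Camera called the salicylate list lower (adjusted p = 6.8e-05, and adjusted p = 0.082 with an estimated correlation).

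The sulfur and pigment lists were not called as lists in WT. Of the sulfate assimilation and cysteine synthesis genes 5 of 18 rose and 2 fell (5 and 2 adjusted over the list alone), with the adenosine phosphosulfate reductase APR2 (AT1G62180, 1.24 ± 0.11), APS2 (AT1G19920, 0.24 ± 0.07) and SERAT2;2 (AT3G13110, 0.36 ± 0.10) up and the glutathione synthesis genes GSH1 (AT4G23100, -0.29 ± 0.07) and GSH2 (AT5G27380, -0.37 ± 0.08) down. Camera gave adjusted p = 0.28. Of the sulfur starvation markers 3 of 12 rose and 0 fell (3 and 0 adjusted over the list alone), with GGCT2;1 (AT5G26220, 1.76 ± 0.17), a gamma-glutamyl cyclotransferase, and LSU2 (AT5G24660, 1.4 ± 0.23) highest. This list had adjusted p = 0.113. The beta-carotene hydroxylases BCH1 (AT4G25700, 1.46 ± 0.17) and BCH2 (AT5G52570, 1.25 ± 0.20) rose while VDE (AT1G08550, -0.59 ± 0.08) and PSY (AT5G17230, -0.44 ± 0.07) fell. Of all carotenoid genes 2 of 10 rose and 4 fell (3 and 5 adjusted over the list alone), with a camera adjusted p = 0.41. The protochlorophyllide oxidoreductases PORA (AT5G54190, -1.17 ± 0.24) and PORB (AT4G27440, -0.57 ± 0.07) fell and HEMA1 (AT1G58290, 0.36 ± 0.10) rose. Of all chlorophyll synthesis genes 1 of 12 rose and 4 fell (3 and 5 adjusted over the list alone), with adjusted p = 0.0998. Among light harvesting genes LHCB1.1 (AT1G29920, 0.60 ± 0.14) rose and LHCB1.4 (AT2G34430, -0.64 ± 0.11) and LHCB4.2 (AT3G08940, -0.52 ± 0.09) fell. Of these genes 2 of 17 rose and 4 fell (2 and 5 adjusted over the list alone), with adjusted p = 0.28. Of the glucosinolate genes 4 of 21 rose and 2 fell (5 and 2 adjusted over the list alone), with MYB34 (AT5G60890, 0.74 ± 0.15) up and CYP83B1 (AT4G31500, -0.91 ± 0.09) down. The glucosinolate list had adjusted p = 0.547. In the dehydration list 2 of 13 rose and 2 fell (2 and 2 adjusted over the list alone), RD20 (AT2G33380, 1.68 ± 0.23) up and RD29A (AT5G52310, -0.88 ± 0.14) down, with adjusted p = 0.66. The thioredoxin-like CDSP32 (AT1G76080, 0.80 ± 0.09) rose and TRXF2 (AT5G16400, -0.66 ± 0.10) fell in the plastid thioredoxin system. There 2 of 13 rose and 1 fell (2 and 1 adjusted over the list alone), with adjusted p = 0.714.

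In 2cysprx, 1246 genes rose and 1134 fell from NL to HL. The shade marker genes HFR1 (3.42 ± 0.26, adjusted p = 2.1e-11) and PIL1 (2.96 ± 0.28, adjusted p = 4.1e-09) and the dehydration gene RD20 (2.86 ± 0.23, adjusted p = 1.1e-10) rose most among the named genes. Of the dehydration genes 5 of 13 rose and 0 fell (6 and 0 adjusted over the list alone), including RD29A (0.59 ± 0.14). Camera called the dehydration list higher (adjusted p = 5.1e-08). Of the shade markers 5 of 8 rose and 0 fell (6 and 0 adjusted over the list alone). The shade list was called higher by camera (adjusted p = 6.2e-15). Likewise 6 of 10 Calvin-Benson genes rose and 0 fell (8 and 0 adjusted over the list alone), with RBCS2B (1.12 ± 0.09) and RBCS3B (AT5G38410, 0.59 ± 0.13) most. The Calvin-Benson list was called higher by camera (adjusted p = 5.1e-08). Of the antioxidant enzymes 7 of 28 rose and 3 fell (10 and 5 adjusted over the list alone), including CAT2 (0.96 ± 0.13) and DHAR1 (AT1G19570, 0.86 ± 0.14). Camera called the antioxidant list higher (adjusted p = 0.00156), also without its 2CPA and 2CPB (adjusted p = 0.00283). With these 2 its mean level was 8.33 on 2cysprx HL replicate 2, where both read highest, and 8.18 on each of the other 3 HL arrays. In the plastid thioredoxin system 5 of 13 rose and 1 fell (6 and 1 adjusted over the list alone), with CDSP32 (0.77 ± 0.09) highest. Camera called this list higher (adjusted p = 2.8e-04). Of the sulfur starvation markers 2 of 12 rose and 0 fell (3 and 0 adjusted over the list alone), GGCT2;1 (1.46 ± 0.17) and SULTR4;2 (AT3G12520, 0.77 ± 0.15). Camera called this list higher (adjusted p = 0.00156). Of the flavonoid genes 0 of 25 rose and 3 fell (0 and 3 adjusted over the list alone), with the flavonol synthase FLS1 (AT5G08640, -0.83 ± 0.15) down. The flavonoid list was called lower by camera (adjusted p = 0.0238, 0.462 with an estimated correlation) and not by fry, a rotation test (adjusted p = 0.13). Of the sulfate assimilation genes, APR2 (0.51 ± 0.11) rose and GSH1 (-0.27 ± 0.07) fell. With only the 8 arrays compared in the fit, 873 genes were called.

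In cyp20-3, 2457 genes rose and 2502 fell from NL to HL. As a group jasmonate genes rose: 17 of 24 members rose and 0 fell (19 and 0 adjusted over the list alone), with the vegetative storage protein gene VSP1 (AT5G24780, 2.60 ± 0.57, adjusted p = 9.4e-04) and the jasmonate repressor gene JAZ7 (AT2G34600, 2.01 ± 0.24, adjusted p = 8.6e-08) at the top. The jasmonate list was called higher by camera (adjusted p = 2.8e-14). In addition 4 of 12 sulfur starvation markers rose and 0 fell (5 and 0 adjusted over the list alone), with GGCT2;1 (1.86 ± 0.17) and LSU2 (1.67 ± 0.23). This list was called higher by camera (adjusted p = 0.0013). Of the sulfate assimilation genes APR2 (1.49 ± 0.11, adjusted p = 6.9e-12) and SERAT1;1 (AT5G56760, 0.36 ± 0.09) rose. Chlorophyll synthesis genes fell: 0 of 12 members rose and 7 fell (0 and 10 adjusted over the list alone), with PORA (-1.76 ± 0.24) and PORB (-0.73 ± 0.07). Camera called this list lower (adjusted p = 1.2e-06). For light harvesting genes 0 of 17 rose and 8 fell (0 and 9 adjusted over the list alone), with LHCB1.4 (-0.99 ± 0.11) lowest. Camera called this list lower (adjusted p = 2.9e-05). In the clock list 2 of 12 rose and 5 fell (3 and 6 adjusted over the list alone), with FKF1 (-1.18 ± 0.11) and TOC1 (AT5G61380, -0.72 ± 0.08) down. The clock list was called lower by camera (adjusted p = 0.00158). The further clock-phased genes moved by 0.255 log2 between the lights.

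In oastlB, 2198 genes rose and 2297 fell from NL to HL. Anthocyanin genes rose together: 20 of 25 members of the flavonoid list rose and 0 fell (21 and 0 adjusted over the list alone), with UF3GT (AT5G54060, 1.95 ± 0.39, adjusted p = 3.1e-04) and GSTF12 (1.93 ± 0.27, adjusted p = 1.9e-06) highest. By camera the flavonoid list was higher (adjusted p = 1.6e-14). Of the heat shock genes 9 of 20 rose and 0 fell (13 and 0 adjusted over the list alone), HSP90.1 (4.42 ± 0.39, adjusted p = 2.5e-10) and HSP70 (4.24 ± 0.34) most. The heat shock list was called higher by camera (adjusted p = 2.7e-09). Of the dehydration genes 8 of 13 rose and 0 fell (10 and 0 adjusted over the list alone), with RD20 (3.26 ± 0.23) and HAI1 (AT5G59220, 1.07 ± 0.23). The dehydration list was called higher by camera (adjusted p = 3.0e-08). Of the sulfate assimilation genes 4 of 18 rose and 3 fell (9 and 3 adjusted over the list alone), with APR2 (0.98 ± 0.11) and APR3 (AT4G21990, 0.80 ± 0.12). Camera called the sulfate assimilation list higher (adjusted p = 0.01, and adjusted p = 0.00306 without OASB). Of 12 sulfur starvation markers, 5 rose and 0 fell (5 and 0 adjusted over the list alone), with GGCT2;1 (2.37 ± 0.17). By camera this list was higher (adjusted p = 2.7e-05). Of 24 jasmonate genes, 14 rose and 0 fell (18 and 0 adjusted over the list alone), with VSP1 (2.80 ± 0.57) and JAZ9 (AT1G70700, 1.71 ± 0.19). By camera the jasmonate list was higher (adjusted p = 1.5e-12). Of the chlorophyll synthesis genes 0 of 12 rose and 10 fell (0 and 11 adjusted over the list alone), with PORA (-1.32 ± 0.24) and PORB (-0.97 ± 0.07). This list was called lower by camera (adjusted p = 6.3e-12). As limits, 2532 genes were called with only the compared arrays in the fit and 2964 without the arrays that stood apart, oastlB HL replicates 2 and 4 among them.

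In the arrays labelled serat2;1, 1541 genes rose and 1643 fell from NL to HL. As a group chlorophyll synthesis genes fell: 0 of 12 members rose and 10 fell (0 and 10 adjusted over the list alone), with PORA (-1.28 ± 0.24, adjusted p = 2.9e-04) and PORB (-0.73 ± 0.07). By camera this list was lower (adjusted p = 3.8e-12). Of the salicylate genes 0 of 19 rose and 7 fell (0 and 9 adjusted over the list alone), with SARD1 (-1.18 ± 0.17, adjusted p = 5.1e-06) and EDS5 (AT4G39030, -1.17 ± 0.16). The salicylate list was called lower by camera (adjusted p = 1.7e-06). Of the shade markers 5 of 8 rose and 0 fell (5 and 0 adjusted over the list alone), with HFR1 (3.13 ± 0.26) and PIL1 (2.46 ± 0.28). Camera called the shade list higher (adjusted p = 1.5e-10). Of the sulfur starvation markers 5 of 12 rose and 0 fell (5 and 0 adjusted over the list alone), with GGCT2;1 (1.95 ± 0.17) and SDI1 (AT5G48850, 1.4 ± 0.26). Camera called this list higher (adjusted p = 0.002). Of the sulfate assimilation genes, APR2 (0.93 ± 0.11) and APR3 (0.76 ± 0.12) rose and GSH1 (-0.26 ± 0.07) fell. With only the compared arrays, 1407 genes were called.

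The light response of each mutant was set against that of WT, with which it shares no array. Across genes, which are not independent replicates, Pearson's r with the WT response was 0.452 in 2cysprx, 0.660 in cyp20-3, 0.568 in oastlB and 0.471 in serat2;1. Of the 5519 genes called in WT, 74.3% had a difference of the same sign in 2cysprx, called there or not, 93.9% in cyp20-3, 84.0% in oastlB and 84.0% in serat2;1, where unrelated signs would give between 49.98% and 50.1%. On those genes the median response in the WT direction was 0.156 log2 in 2cysprx, 0.356 in cyp20-3, 0.272 in oastlB and 0.236 in serat2;1, against a median size of 0.509 in WT, where the genes were selected. Genes called higher in both WT and mutant numbered 726 for 2cysprx (128 for independent lists), 1559 for cyp20-3 (252), 1202 for oastlB (225) and 968 for serat2;1 (158). Those called lower in both numbered 448 (109), 1450 (240), 1141 (220) and 838 (157), and those called in opposite directions 125, 17, 62 and 29.

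**Figure D3:**
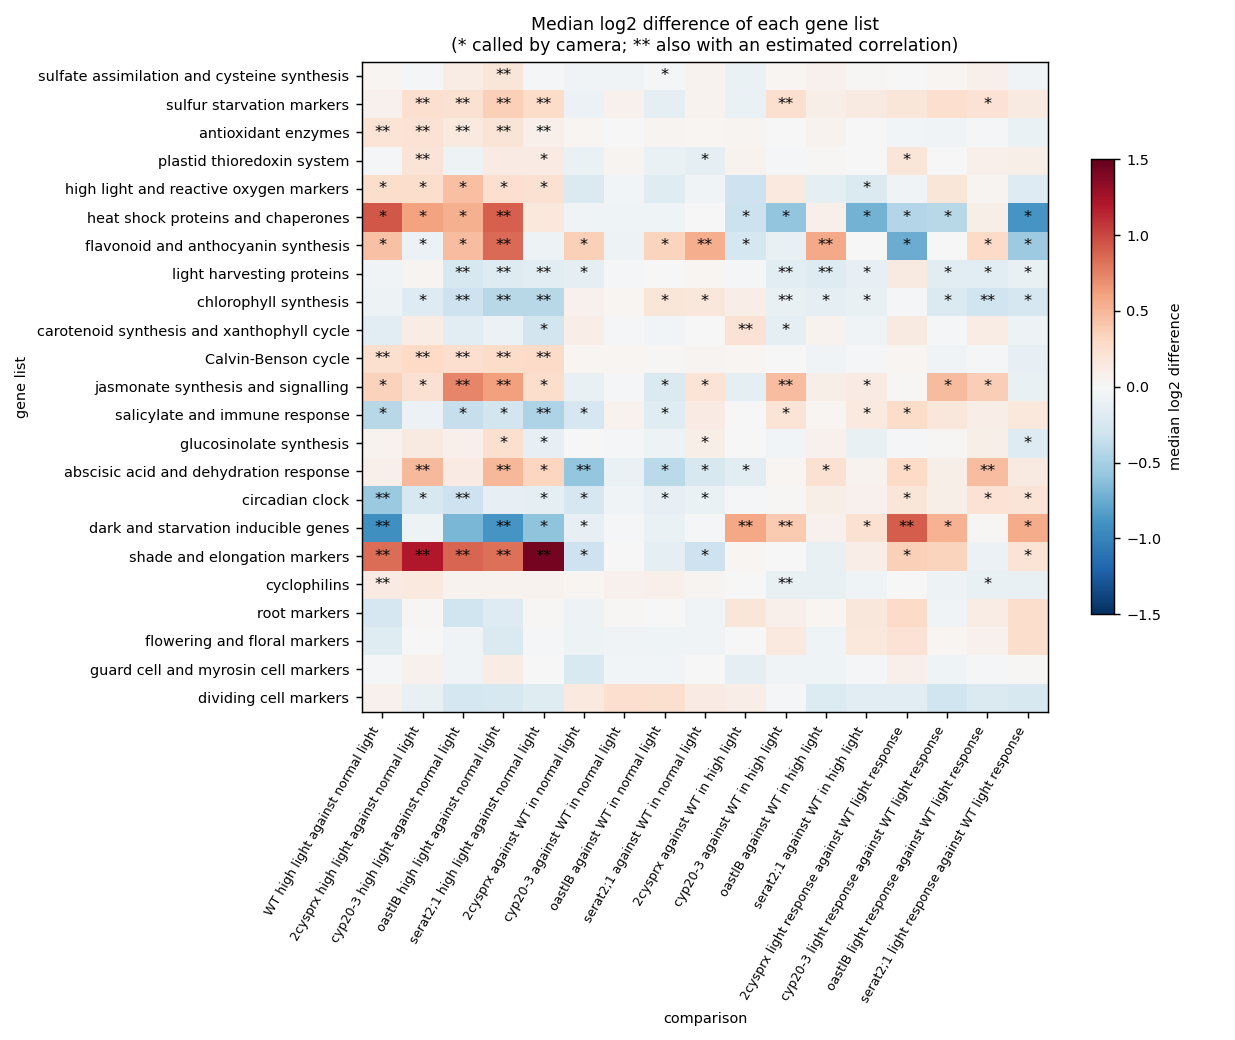
Median log2 difference of the genes of each list (rows) in each of the 17 comparisons (columns), red for higher and blue for lower. * marks lists called by camera with the preset correlation of 0.01 and ** those also called with an estimated correlation, as for shade markers in all 5 light responses.

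In normal light, 2cysprx differed most from WT, with 1556 genes higher and 1263 lower. Beside 2CPA and 2CPB, the largest differences were AT4G05370 (3.05 ± 0.22, adjusted p = 3.0e-11), ST2A (AT5G07010, -2.63 ± 0.29, adjusted p = 2.1e-07), a hydroxyjasmonate sulfotransferase gene that lies near a targeted locus, MRD1 (AT1G53480, -2.20 ± 0.21, adjusted p = 1.1e-08) and AT5G38005 (-1.98 ± 0.35). TOM7-2 (AT1G64220, 1.71 ± 0.39), GPT2 (1.59 ± 0.26, adjusted p = 6.1e-05), AT1G51380 (1.57 ± 0.28) and NAC044 (AT3G01600, 1.55 ± 0.26) were higher. As a group dehydration genes were lower: 0 of 13 members were higher and 7 lower (0 and 8 adjusted over the list alone), with RD29A (-1.65 ± 0.14) and RD20 (-1.34 ± 0.23). By camera the dehydration list was lower (adjusted p = 5.8e-10). By contrast 9 of 25 flavonoid genes were higher and 0 lower (9 and 0 adjusted over the list alone), with FLS1 (1.11 ± 0.15) and the chalcone synthase CHS (AT5G13930, 1.01 ± 0.17). Camera called the flavonoid list higher (adjusted p = 2.9e-06, and adjusted p = 0.207 with an estimated correlation). In the clock list 2 of 12 were higher and 6 lower (2 and 6 adjusted over the list alone), PRR9 (1.34 ± 0.20) up and ELF4 (-1.27 ± 0.16) down. By camera the clock list was lower (adjusted p = 0.00418, 0.18 with an estimated correlation). The further clock-phased genes stood 0.917 log2 toward an earlier hour, 9 of 10 on that side and 5 of them called. Of 11 dark inducible genes, 0 were higher and 4 lower (0 and 4 adjusted over the list alone), with SEN1 (AT4G35770, -1.5 ± 0.30) and TPS11 (-1.04 ± 0.24). By camera the dark inducible list was lower (adjusted p = 0.0155, 0.238 with an estimated correlation and 0.0565 without the arrays that stood apart). Of 8 shade markers, 0 were higher and 3 lower (0 and 3 adjusted over the list alone), with PIL1 (-1.2 ± 0.28) and IAA29 (AT4G32280, -1.08 ± 0.19). The shade list was called lower by camera (adjusted p = 0.0155, 0.207 with an estimated correlation and 0.198 among the brighter genes). In the sulfate list APS4 (AT5G43780, -0.61 ± 0.10) was lower and APR2 (0.53 ± 0.11) higher. With only the 8 arrays compared in the fit 618 genes were called, and 1649 without the arrays that stood apart, among them 2cysprx NL replicate 2 and WT NL replicate 1.

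In cyp20-3 only 6 genes were higher and 7 lower than in WT in normal light by limma, while 2549 had an unadjusted p under 0.05. Besides CYP20-3, MRD1 (-2.29 ± 0.21, adjusted p = 1.5e-08) was lower and FLN1 (AT3G54090, 0.58 ± 0.09, adjusted p = 0.00246), a fructokinase-like gene of plastid transcription, higher, and these kept their calls when any single array was left out. With only the compared arrays MRD1 kept its call (adjusted p = 0.0159) and FLN1 lost it (adjusted p = 0.225, against 3.2e-04 to 0.0278 in its other fits). PTAC14 (AT4G20130, 0.40 ± 0.08), another plastid transcription gene, MIR169i (AT3G26812, 1.12 ± 0.22), AT5G19750 (0.38 ± 0.07) and AT3G62040 (1.09 ± 0.19), which lies next to the targeted locus, were also higher, and QQS (AT3G30720, -1.02 ± 0.20), RL1 (AT4G39250, -1.0 ± 0.20) and AT1G68600 (-0.87 ± 0.16) lower. Of the 23 gene lists, camera called 0 and fry 1. The clock-phased genes stood at -0.0941 log2. Without WT NL replicate 4, the adjusted p of PTAC14, MIR169i, AT5G19750, QQS, RL1 and AT1G68600 was 0.203, 0.159, 0.178, 0.181, 0.189 and 0.159, in that order, and that of AT3G62040 without cyp20-3 NL replicate 4 was 0.0857. The count was 7, 3, 5 and 7 without cyp20-3 NL replicate 1, 2, 3 or 4 and 6, 5 and 3 without WT NL replicate 1, 2 or 4, 2 (0 higher and 2 lower) with only the compared arrays, 8 with array weights and 6 without the arrays that stood apart. It was 30 (20 higher and 10 lower) with an intensity trend and 41 (30 and 11) among the brighter genes alone.

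In oastlB in normal light, 598 genes were higher and 355 lower than in WT. After OASB, MRD1 (-2.23 ± 0.21, adjusted p = 3.1e-08) was lowest, followed by AT5G53610 (-1.21 ± 0.25, adjusted p = 0.00455), while AT1G13650 (1.1 ± 0.18, adjusted p = 4.5e-04), AT1G68238 (1.02 ± 0.18), AT1G63250 (0.96 ± 0.20), AT4G36850 (0.94 ± 0.16) and AT1G11684 (0.89 ± 0.18) were highest. Of 18 sulfate assimilation genes, 0 were higher and 2 lower (1 and 3 adjusted over the list alone), with OASB itself 1 of those lower. The sulfate assimilation list was called lower by camera (adjusted p = 0.0325, and adjusted p = 0.153 with an estimated correlation), but not without OASB (adjusted p = 0.538). Of 13 dehydration genes, 0 were higher and 5 lower (0 and 6 adjusted over the list alone), with RD29A (-0.82 ± 0.14). Camera called the dehydration list lower (adjusted p = 6.0e-06, and adjusted p = 0.087 with an estimated correlation). Of 12 chlorophyll synthesis genes, 2 were higher and 0 lower (7 and 0 adjusted over the list alone). Camera called the chlorophyll synthesis list higher (adjusted p = 6.3e-05, and adjusted p = 0.087 with an estimated correlation). In the clock list 0 of 12 were higher and 4 lower (2 and 6 adjusted over the list alone), with ELF4 (-1.01 ± 0.16) and TOC1 (-0.56 ± 0.08) lower. Camera called the clock list lower (adjusted p = 0.00248, 0.104 with an estimated correlation). The clock-phased genes stood 0.728 log2 toward an earlier hour, 8 of 10 on that side and 2 of them called. The count was 420 without oastlB NL replicate 3 and 621 and 566 without WT NL replicate 1 or 4, and 1579 among the brighter genes alone. With only the 8 arrays compared in the fit, limma called 2 genes.

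In the arrays labelled serat2;1 in normal light, 444 genes were higher and 230 lower than in WT. As a group flavonoid and anthocyanin genes were higher: 7 of 25 members were higher and 0 lower (15 and 0 adjusted over the list alone), with the anthocyanin malonyltransferase gene 5MAT (AT3G29590, 1.04 ± 0.22, adjusted p = 0.00578). The flavonoid list was called higher by camera (adjusted p = 4.4e-15). MRD1 (-2.16 ± 0.21, adjusted p = 1.4e-07), ELF4 (-1.23 ± 0.16, adjusted p = 3.5e-05), AT5G44260 (-1.12 ± 0.21), AT2G33830 (-1.07 ± 0.17) and RVE2 (AT5G37260, -1.06 ± 0.22) were lowest, and PRR9 (1.2 ± 0.20, adjusted p = 7.3e-04) was among the highest. Of 12 clock genes, 2 were higher and 4 lower (2 and 6 adjusted over the list alone), with PRR9 and ELF4 among them. The clock list was called lower by camera (adjusted p = 0.00921, 0.177 with an estimated correlation). The clock-phased genes stood 0.841 log2 toward an earlier hour, 8 of 10 on that side and 3 of them called. Of 12 chlorophyll synthesis genes, 2 were higher and 0 lower (4 and 0 adjusted over the list alone), with HEMA1 (0.48 ± 0.10). The chlorophyll synthesis list was called higher by camera (adjusted p = 1.7e-04, and adjusted p = 0.122 with an estimated correlation). Of 13 dehydration genes, 0 were higher and 3 lower (0 and 4 adjusted over the list alone), with RD29A (-0.77 ± 0.14) and NCED3 (AT3G14440, -0.73 ± 0.16). The dehydration list was called lower by camera (adjusted p = 0.00146, and adjusted p = 0.225 with an estimated correlation). The count was 369 and 352 without serat2;1 NL replicate 2 or 4 and 398 and 335 without WT NL replicate 1 or 4, and 1051 among the brighter genes alone. With only the 8 arrays compared in the fit, limma called 0 genes, with 3567 at an unadjusted p under 0.05.

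In high light, 352 genes were higher and 264 lower in 2cysprx than in WT. AT4G05370 (2.65 ± 0.22, adjusted p = 1.9e-09), AT2G18193 (2.55 ± 0.26, adjusted p = 1.2e-07), NAC044 (2.36 ± 0.26, adjusted p = 8.3e-07), the ubiquitin ligase gene PUB54 (AT1G01680, 1.89 ± 0.30) and AT5G56100 (1.62 ± 0.18) were highest, and AT3G01345 (-4.36 ± 0.51, adjusted p = 1.7e-06) and HSFA2 (-2.51 ± 0.43, adjusted p = 5.7e-04) were, with 2CPA and 2CPB, lowest. As a group carotenoid genes were higher: 3 of 10 members were higher and 0 lower (6 and 0 adjusted over the list alone), with the lycopene cyclase LCYB (AT3G10230, 0.35 ± 0.08). Camera called the carotenoid list higher (adjusted p = 3.7e-05). Also 3 of 11 dark inducible genes were higher and 0 lower (7 and 0 adjusted over the list alone), with TPS8 (AT1G70290, 0.86 ± 0.18). Camera called the dark inducible list higher (adjusted p = 1.7e-05). Of 20 heat shock genes, 0 were higher and 4 lower (0 and 4 adjusted over the list alone), with HSFA2 and HSP101 (AT1G74310, -2.04 ± 0.41) lowest. By camera the heat shock list was lower (adjusted p = 1.0e-04, and adjusted p = 0.334 with an estimated correlation), but not by fry (adjusted p = 0.0937). For the clock-phased genes the value was 0.133 log2. The count was 385, 392 and 375 without 2cysprx HL replicate 1, 3 or 4 and 371 and 300 without WT HL replicate 3 or 4, 151 with only the compared arrays and 1036 with array quality weights.

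In high light, 392 genes were higher and 230 lower in cyp20-3 than in WT. The transcription factor gene WRKY18 (AT4G31800, 2.46 ± 0.23, adjusted p = 9.5e-09), the xyloglucan endotransglucosylase TCH4 (AT5G57560, 2.32 ± 0.20, adjusted p = 1.3e-09), EXO (AT4G08950, 2.31 ± 0.24, adjusted p = 6.3e-08), AT4G16563 (2.15 ± 0.17) and the anion channel SLAH3 (AT5G24030, 2.1 ± 0.19) were highest, and AT3G01345 (-4.28 ± 0.51), MRD1 (-2.27 ± 0.21), the heat coactivator MBF1C (AT3G24500, -2.13 ± 0.27, adjusted p = 3.3e-06) and PRR9 (-1.76 ± 0.20, adjusted p = 4.6e-07) were, with CYP20-3, lowest. Of the jasmonate genes 8 of 24 were higher and 0 lower (11 and 0 adjusted over the list alone), with JAZ6 (AT1G72450, 0.86 ± 0.13). Camera called the jasmonate list higher (adjusted p = 2.9e-13). Of the dark inducible genes 2 of 11 were higher and 0 lower (3 and 0 adjusted over the list alone), DIN10 (AT5G20250, 2.01 ± 0.20) and TPS8 (1.66 ± 0.18). The dark inducible list was called higher by camera (adjusted p = 9.8e-06). Of 12 sulfur starvation markers, 1 was higher and 0 lower (3 and 0 adjusted over the list alone). The sulfur starvation list was called higher by camera (adjusted p = 0.00188), but not among the brighter genes (adjusted p = 0.108). Of 17 light harvesting genes, 0 were higher and 2 lower (0 and 9 adjusted over the list alone), with LHCB1.2 (AT1G29910, -0.40 ± 0.08). By camera this list was lower (adjusted p = 1.6e-09). Of 12 chlorophyll synthesis genes, 0 were higher and 2 lower (0 and 4 adjusted over the list alone), with GUN4 (AT3G59400, -0.73 ± 0.14) and CAO (AT1G44446, -0.34 ± 0.07). By camera this list was lower (adjusted p = 9.8e-06). Of 13 cyclophilins, 0 were higher and 1 lower (0 and 1 adjusted over the list alone), with CYP20-3 itself as the called member. With CYP20-3 in the list camera called it lower (adjusted p = 6.4e-04), but not for the other 12 cyclophilins (adjusted p = 0.295, and adjusted p = 0.329 with an estimated correlation). The clock-phased genes stood at -0.885 log2, with 0 of 10 toward an earlier hour and 5 called toward a later one. The count was 409 without cyp20-3 HL replicate 4, 390 with only the compared arrays and 1047 with array quality weights.

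In high light, 125 genes were higher and 113 lower in oastlB than in WT. NUDT24 (AT5G19470, 2.77 ± 0.38, adjusted p = 1.9e-04), of the Nudix hydrolase family, and AHP4 (AT3G16360, 1.61 ± 0.28, adjusted p = 0.00337), a histidine phosphotransfer protein gene, were highest, with AT1G03940 (1.4 ± 0.27). After OASB, AT3G01345 (-3.65 ± 0.51), MRD1 (-2.34 ± 0.21) and the auxin-responsive SAUR22 (AT5G18050, -1.64 ± 0.26) were lowest. In the flavonoid and anthocyanin list 8 of 25 were higher and 0 lower (20 and 0 adjusted over the list alone), with the dihydroflavonol reductase DFR (AT5G42800, 1.62 ± 0.37, adjusted p = 0.027) and GSTF12 (1.32 ± 0.27). By camera the flavonoid list was higher (adjusted p = 4.4e-21). Of 17 light harvesting genes, 1 was higher and 3 lower (1 and 7 adjusted over the list alone). Camera called this list lower (adjusted p = 3.3e-06). Of 12 chlorophyll synthesis genes, 0 were higher and 2 lower (0 and 3 adjusted over the list alone), with PORB (-0.38 ± 0.07). Camera called the chlorophyll synthesis list lower (adjusted p = 3.6e-05, and adjusted p = 0.0553 with an estimated correlation). The clock-phased genes stood at -0.197 log2. DFR lost its call without oastlB HL replicate 4 (1.47, adjusted p = 0.112), as in 6 of the 8 fits that left out 1 array, and GSTF12 lost its call without oastlB HL replicate 4 (1.16, adjusted p = 0.079). The count was 133, 149 and 69 without oastlB HL replicate 2, 3 or 4 and 113, 130 and 73 without WT HL replicate 2, 3 or 4, 31 with only the compared arrays, 20 without the arrays that stood apart and 367 with an intensity trend.

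In high light, 143 genes were higher and 123 lower in the arrays labelled serat2;1 than in WT. Of 20 heat shock genes, 0 were higher and 7 lower (0 and 9 adjusted over the list alone), with HSFA2 (-2.99 ± 0.43, adjusted p = 1.9e-04) and HSP101 (-2.25 ± 0.41, adjusted p = 0.0034). Camera called the heat shock list lower (adjusted p = 1.4e-12, and adjusted p = 0.145 with an estimated correlation). The small heat shock protein gene AT1G59860 (-2.26 ± 0.37, adjusted p = 0.00108) was also low. AT3G01345 (-4.08 ± 0.51) was lowest. DIN10 (1.42 ± 0.20, adjusted p = 1.4e-04) and PR4 (1.35 ± 0.22, adjusted p = 0.001) were higher. Of 11 dark inducible genes, 2 were higher and 0 lower (3 and 0 adjusted over the list alone), with DIN10 among them. By camera the dark inducible list was higher (adjusted p = 8.5e-04, and adjusted p = 0.145 with an estimated correlation). The clock-phased genes stood at -0.625 log2, with 1 of 10 toward an earlier hour and 4 called toward a later one. The count was 109 and 110 without serat2;1 HL replicate 3 or 4 and 163, 95 and 76 without WT HL replicate 2, 3 or 4, and limma called 2 genes with only the compared arrays in the fit.

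The light response differed from that of WT for 1694 genes in 2cysprx, 710 higher and 984 lower. Here and below, unequal harvest hours would enter it too. GPT2 (-3.38 ± 0.37, adjusted p = 9.4e-07) differed most, with a response of 3.72 in WT and 0.34 in 2cysprx. SEN1 (2.65 ± 0.43, adjusted p = 1.2e-04), ST2A (2.52 ± 0.41, adjusted p = 1.4e-04) and the chloroplast DnaJ gene J8 (AT1G80920, 2.23 ± 0.24, adjusted p = 9.4e-07) had the most positive differences and HSFA2 (-2.48 ± 0.61, adjusted p = 0.00956) a negative one. Of the dark inducible genes 6 of 11 responded higher and 0 lower (6 and 0 adjusted over the list alone), with TPS11 (1.70 ± 0.34). Camera called the dark inducible list higher (adjusted p = 3.2e-06). Of the flavonoid genes 0 of 25 responded higher and 8 lower (0 and 12 adjusted over the list alone), with CHS (-1.52 ± 0.23) and FLS1 (-1.28 ± 0.21). Camera called the flavonoid list lower (adjusted p = 1.0e-09, 0.108 with an estimated correlation). Of the dehydration genes 3 of 13 responded higher and 0 lower (5 and 0 adjusted over the list alone), with RD29A (1.48 ± 0.19). By camera the dehydration list was higher (adjusted p = 2.8e-04, 0.158 with an estimated correlation). In the sulfate list APR2 (-0.72 ± 0.16) responded less, as did DHAR2 (-1.09 ± 0.24) and the superoxide dismutase FSD3 (AT5G23310, -0.64 ± 0.14) among antioxidant enzymes. Of 12 clock genes, 3 responded higher and 1 lower (5 and 1 adjusted over the list alone), with ELF4 (0.93 ± 0.22) above and PRR9 (-1.81 ± 0.29) below the WT response. By camera the clock list was higher (adjusted p = 0.0192, 0.208 with an estimated correlation and 0.0609 without the arrays that stood apart). The clock-phased genes moved by 0.333 log2 in 2cysprx against 1.14 in WT. With only the compared arrays 1006 genes were called, and 1042 without the arrays that stood apart.

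In cyp20-3 the light response differed from WT for 238 genes, 175 higher and 63 lower. WRKY18 (2.66 ± 0.33, adjusted p = 1.5e-05), SLAH3 (2.26 ± 0.26, adjusted p = 1.3e-05) and AT1G02610 (2.22 ± 0.48) responded more and MBF1C (-2.05 ± 0.39, adjusted p = 0.00305) less. Of 24 jasmonate genes, 2 responded higher and 0 lower (8 and 0 adjusted over the list alone), with JAZ2 (AT1G74950, 0.80 ± 0.16). The jasmonate list was called higher by camera (adjusted p = 2.7e-09, and adjusted p = 0.0895 with an estimated correlation). Of 11 dark inducible genes, 2 responded higher and 0 lower (3 and 1 adjusted over the list alone), with DIN10 (1.92 ± 0.28) and TPS8 (1.68 ± 0.26). The dark inducible list was called higher by camera (adjusted p = 2.3e-04, and adjusted p = 0.0895 with an estimated correlation). HSFA2 (-2.58 ± 0.61) responded lower, but it lost its call without WT HL replicate 4 (-2.01, adjusted p = 0.0825), as in 9 of the 16 fits that left out 1 array. The count was 131 without cyp20-3 NL replicate 1, 155 and 153 without WT NL replicate 3 or 4, 119 and 120 without cyp20-3 HL replicate 2 or 4 and 155 without WT HL replicate 4, and 142 with only the compared arrays.

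In oastlB the light response differed from WT for 779 genes, 324 higher and 455 lower. NUDT24 (2.67 ± 0.54, adjusted p = 0.00479), AHP4 (2.46 ± 0.40, adjusted p = 8.1e-04) and AT1G64360 (1.79 ± 0.36) responded more and the MYB-related gene EPR1 (AT1G18330, -1.47 ± 0.28, adjusted p = 0.00305) less. In the dehydration list 4 of 13 responded higher and 0 lower (7 and 0 adjusted over the list alone), with RD20 (1.57 ± 0.32) and RD29A (1.33 ± 0.19). Camera called the dehydration list higher (adjusted p = 4.1e-08). In the chlorophyll synthesis list 0 of 12 responded higher and 5 lower (0 and 8 adjusted over the list alone), with GUN4 (-0.97 ± 0.20) and HEMA1 (-0.63 ± 0.14). By camera this list was lower (adjusted p = 2.4e-08). Of 12 clock genes, 2 responded higher and 0 lower (5 and 1 adjusted over the list alone), with ELF4 (1.39 ± 0.22) and TOC1 (0.67 ± 0.11). Camera called the clock list higher (adjusted p = 0.00111, and adjusted p = 0.0516 with an estimated correlation). The clock-phased genes moved by 0.242 log2 against 1.14 in WT. The count was 497 and 448 without oastlB NL replicate 2 or 3, 434 and 502 without WT NL replicate 1 or 4, 440 without oastlB HL replicate 4 and 497, 515 and 414 without WT HL replicate 1, 2 or 4. It was 140 with only the compared arrays, 163 without the arrays that stood apart and 1342 among the brighter genes alone.

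In the arrays labelled serat2;1 the light response differed from WT for 638 genes, 278 higher and 360 lower. Of the heat shock genes 0 of 20 responded higher and 4 lower (0 and 6 adjusted over the list alone), with HSFA2 (-2.69 ± 0.61, adjusted p = 0.0152). The heat shock list was called lower by camera (adjusted p = 2.3e-07, and adjusted p = 0.174 with an estimated correlation). Lower responses were found for the small heat shock protein genes AT1G59860 (-2.28 ± 0.53) and AT1G54050 (-2.20 ± 0.44, adjusted p = 0.00531). AT2G33830 (1.88 ± 0.24, adjusted p = 6.0e-05), BT2 (1.84 ± 0.41) and AT1G15125 (1.84 ± 0.42), which fell in WT, had positive differences. Of 25 flavonoid genes, 0 responded higher and 1 lower (0 and 7 adjusted over the list alone), with CHS (-1.01 ± 0.23). The flavonoid list was called lower by camera (adjusted p = 2.3e-07, and adjusted p = 0.174 with an estimated correlation). Of 12 chlorophyll synthesis genes, 0 responded higher and 3 lower (0 and 6 adjusted over the list alone), with GUN4 (-0.85 ± 0.20) and HEMA1 (-0.83 ± 0.14). Camera called the chlorophyll synthesis list lower (adjusted p = 4.5e-06, and adjusted p = 0.0853 with an estimated correlation). Of 12 clock genes, 4 responded higher and 2 lower (5 and 2 adjusted over the list alone), with ELF4 (1.36 ± 0.22) above and PRR9 (-2.18 ± 0.29) below the WT response. The clock list was called higher by camera (adjusted p = 0.0291, and adjusted p = 0.211 with an estimated correlation). The clock-phased genes moved by -0.194 log2 against 1.14 in WT. The count was 374 without serat2;1 NL replicate 4, 379 and 421 without WT NL replicate 1 or 4, 339 and 328 without serat2;1 HL replicate 3 or 4 and 422 and 366 without WT HL replicate 3 or 4, and 184 with only the compared arrays.

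**Figure D4:**
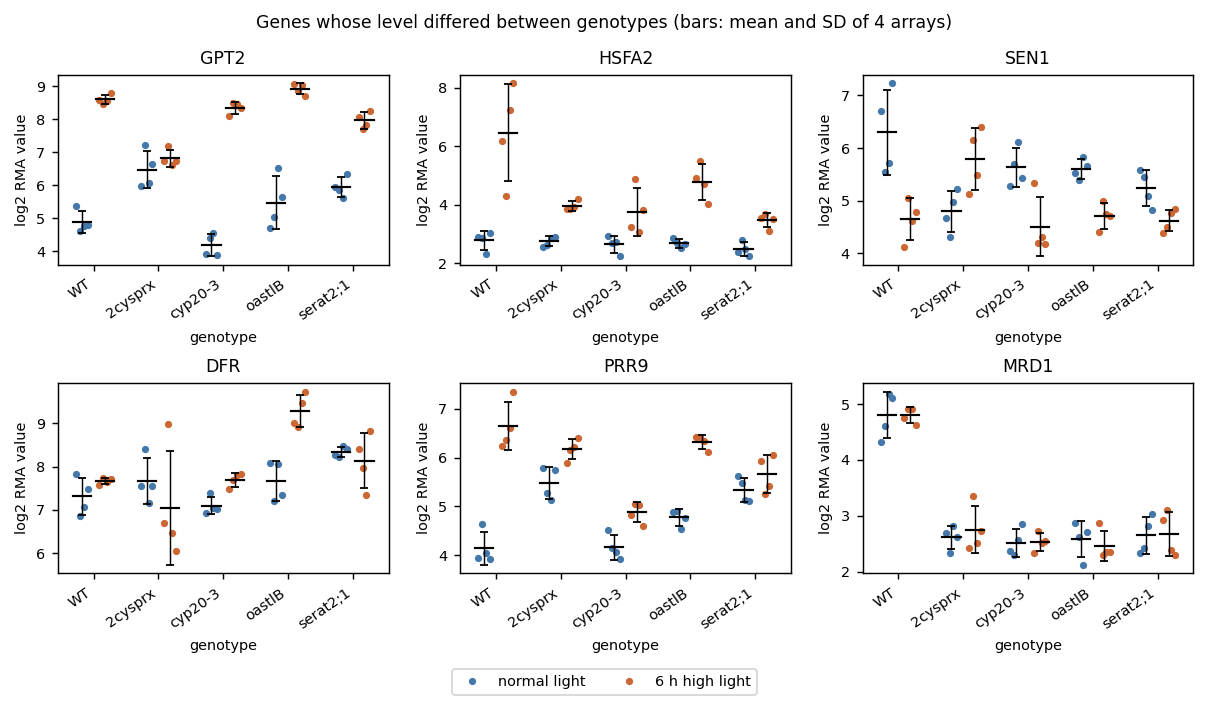
Log2 level of GPT2, HSFA2, SEN1, DFR, PRR9 and MRD1 on each of the 40 arrays (points) by genotype and light, with the group mean and SD (n = 4). GPT2 rises by 3.72 in WT and starts at a 1.59 higher level in 2cysprx in NL, and the differences of MRD1 from WT lie between -2.05 and -2.34 in the 4 mutants.

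Differences from WT were compared between mutants, which share the WT arrays. In normal light, 3 genes were called higher in all 4 mutants (FLN1, AT5G19750 and AT3G27180, the last chosen after its values were seen) and 1 lower, MRD1, which was named for its lowered transcript in a methionine-accumulating mutant. In high light 0 genes were called higher and 7 lower in all 4 mutants, among them MRD1, HSFA2 and AT3G01345. When 1 array was left out, MRD1 stayed called in all 4 mutants in 20 of 20 fits in either light and AT3G01345 in HL in 20, but HSFA2 in 3, and in NL FLN1 and AT5G19750 in 13 and AT3G27180 in 14. With only the compared arrays 0 genes were called in all 4 in NL and 2 in HL, MRD1 and AT3G01345. The 3 higher in NL became 14 with an intensity trend, 26 among the brighter genes, 1 without the arrays that stood apart, 1 without cyp20-3 NL replicate 1, 2 or 3 or WT NL replicate 1 or 2, 0 without WT NL replicate 4, 5 without 2cysprx NL replicate 4 and 6 without WT NL replicate 3. The 7 lower in HL became 3 among the brighter genes, 2 without the arrays that stood apart, 4 without oastlB HL replicate 4 or WT HL replicate 3, 3 without WT HL replicate 4 and 14 without WT HL replicate 2. The 1 lower in NL became 2 with the trend or without oastlB NL replicate 3 and 3 without WT NL replicate 3, and the 0 higher in HL 1 with the trend or without serat2;1 or WT HL replicate 3 and 2 among the brighter genes. Across genes, r between the differences from WT in NL was 0.650 for 2cysprx and oastlB, 0.604 for 2cysprx and serat2;1, 0.616 for oastlB and serat2;1, 0.472 for 2cysprx and cyp20-3, 0.529 for cyp20-3 and oastlB and 0.527 for cyp20-3 and serat2;1, where unchanged groups simulated with a shared, also simulated, WT group gave 0.5002. With WT arrays split into 2 and 2, these fell to 0.0979 to 0.278. In the same order, the covariance minus the simulated 0.0150 was 0.0251, 0.0226, 0.0169, 0.0108, 0.00909 and 0.00923. In HL, r was 0.579 for oastlB and serat2;1, 0.519 for 2cysprx and serat2;1, 0.480 for cyp20-3 and serat2;1, 0.443 for 2cysprx and oastlB, 0.355 for 2cysprx and cyp20-3 and 0.273 for cyp20-3 and oastlB (simulated 0.499). The split gave 0.0370 to 0.307, and the covariance differences were 0.0185, 0.0139, 0.0107, 0.00950, 0.00319 and -0.000472. In NL, 533 genes were called higher and 272 lower in both 2cysprx and oastlB, 370 and 173 in 2cysprx and serat2;1, 286 and 115 in oastlB and serat2;1, and at most 4 and 2 in pairs with cyp20-3. Independent lists would give 33.4 and 16.1, 24.8 and 10.4, and 9.54 and 2.93 for the first 3 pairs, without the shared WT arrays, and simulated unchanged groups 0, without the effects. With WT arrays split, which leaves fewer arrays per test, these counts averaged 172 and 63.8, 105 and 45, and 47.2 and 19.7 (9.12 and 3.15, 5.99 and 2.195, and 1.35 and 0.339 for independent lists). In HL 40 and 53 genes were shared by 2cysprx and cyp20-3, 17 and 20 by 2cysprx and oastlB, 42 and 44 by 2cysprx and serat2;1, 7 and 19 by cyp20-3 and oastlB, 46 and 59 by cyp20-3 and serat2;1 and 20 and 20 by oastlB and serat2;1, with 13, 3, 0, 4, 2 and 1 called in opposite directions (0 in each NL pair). The split left at most 7.67 and 12.2 of them on average.

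Markers of other material that a shoot sample could hold were tested alongside. Root markers, flowering and floral markers, guard cell and myrosin cell markers and dividing cell markers were called in 0 of the 17 comparisons by camera, the lowest adjusted p being 0.108, 0.277, 0.0542 and 0.0710.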

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

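The tests of a wrong genotype and of MRD1 were chosen only after the result was seen. Within groups, 3 values of targeted genes lay far from the other 3 arrays: 2CPA on 2cysprx HL replicate 2 (9.0 against 5.13 to 5.78), 2CPA on oastlB HL replicate 4 (10.26 against 10.75 to 10.81) and 2CPB on cyp20-3 HL replicate 1 (9.58 against 9.27 to 9.32). These are 3 of 90 group tests, where chance gives about 1 in 20. Among 201 named genes, 123 of 2010 gene and group pairs (6.12%) stood out in this way.

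The high 2CPA level on 2cysprx HL replicate 2 was weighed against technical explanations. An array of another genotype under this label is argued against, since the lowest HL array of the other genotypes lay 1.26 log2 higher. Mixed-in RNA stays open: 2CPA alone would need 26.2% foreign RNA, while 8 other genes that mark the genotype gave a median of 12.1% (bootstrap SD 11.3). The prediction also asked for a share above those of the other 3 arrays, which was not met, but they gave -12.7%, 44.1% and 7.80%, a spread wider than the share to be resolved, so that criterion was judged unfit after the result was seen. No biological explanation was tested.

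MRD1 was lower in all 8 comparisons of a mutant with WT, by -2.05 to -2.34. Chance values of the shared WT arrays are argued against, since the smallest ratio of difference to standard error was 9.80 and the WT arrays of the lights differ. In serat2;1 the difference was at least 0.936 of the median of the other mutants. Both a difference between the WT plants and the line the mutants came from and a shared effect of the mutations predict such a value, so these cannot be told apart and stay open. HEI10, the neighbouring gene (chosen after its values were seen), was called lower in all 4 mutants in HL (-1.06 to -1.25) and in 3 in NL (-0.76 to -0.82, with -0.755 and adjusted p = 0.132 in cyp20-3).

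The clock index in NL stood at 0.917 in 2cysprx, 0.728 in oastlB and 0.841 in serat2;1, as an earlier harvest than in WT predicts. Of its 10 genes 9, 8 and 8 lay on that side but only 5, 2 and 3 were called. COR27 and AT4G33980 (-0.81 to -1.25), called in all 3, carried the evening side, with BOA and GRP7 at -0.28 to 0.07 and uncalled. The clock list, seen before the index was tested and called lower by camera in all 3, lost these calls with an estimated correlation (adjusted p = 0.18, 0.104 and 0.177). A single WT array is argued against, since leaving 1 out gave at least 0.851, 0.649 and 0.768. Harvest hours are not given and a genotype effect on the clock would give the same values. Both stay open, as do unequal hours within WT (1.14 between the lights). In HL the index lay toward a later hour in cyp20-3 (-0.885, 5 of 10 called) and serat2;1 (-0.625, 4 called), and at 0.133 in 2cysprx and -0.197 in oastlB.

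Other splits of the 8 arrays were fitted for each comparison. The real split gave the most calls, 1 of 35, the lowest share possible, unadjusted over comparisons. In NL the 13 of cyp20-3 included CYP20-3 and MRD1 and became 3 to 19 without 1 array. The real count and the highest other were 5519 and 32 for the WT light response, 2380 and 12 for 2cysprx, 4959 and 2 for cyp20-3, 4495 and 96 for oastlB and 3184 and 3 for serat2;1. In the same order of mutants they were 2819 and 247, 13 and 2, 953 and 19, and 674 and 1 in NL, and 616 and 3, 622 and 4, 238 and 10, and 266 and 10 in HL.

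The light response differed from WT for 1694 genes in 2cysprx, 238 in cyp20-3, 779 in oastlB and 638 in serat2;1. Harvest hours were not separated from it. The real split had the most calls of 100 (highest other 700, 2, 144 and 163). The genes with the most positive and negative differences were SEN1 (2.65), ST2A (2.52), J8 (2.23), GPT2 (-3.38), AT3G01345 (-2.60) and HSFA2 (-2.48) in 2cysprx, WRKY18 (2.66), SLAH3 (2.26), AT1G02610 (2.22), HSFA2 (-2.58), MBF1C (-2.05) and MIR169m (-1.85) in cyp20-3, NUDT24 (2.67), AHP4 (2.46), AT1G64360 (1.79), SAUR20 (-1.63), AT4G22517 (-1.53) and EPR1 (-1.47) in oastlB, and AT2G33830 (1.88), BT2 (1.84), AT1G15125 (1.84), HSFA2 (-2.69), AT1G59860 (-2.28) and AT1G54050 (-2.20) in serat2;1. Some lost their call without 1 array: AT3G01345 without WT NL replicate 1 (-2.10, adjusted p = 0.0733), HSFA2 in cyp20-3 (-2.01, adjusted p = 0.0825) and MIR169m (-1.54, adjusted p = 0.144) without WT HL replicate 4, and SAUR20 (-1.33, adjusted p = 0.119) and AT4G22517 (-1.36, adjusted p = 0.101) without oastlB HL replicate 4.

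The lists that camera called for this difference with its preset correlation had the medians below. Of these calls 1 of 8 in 2cysprx (dark inducible), 0 of 5 in cyp20-3, 2 of 8 in oastlB (dehydration and chlorophyll synthesis) and 0 of 8 in serat2;1 held with an estimated correlation, and fry also called 6, 4, 6 and 8. In 2cysprx they were 0.18 for the plastid thioredoxin system, -0.43 for heat shock, -0.74 for flavonoids, 0.27 for salicylate, 0.30 for dehydration, 0.18 for the clock, 0.91 for dark inducible genes and 0.36 for shade markers. In cyp20-3 they were -0.42 for heat shock, -0.15 for light harvesting, -0.21 for chlorophyll synthesis, 0.47 for jasmonate and 0.53 for dark inducible genes. In oastlB they were 0.22 for sulfur starvation, 0.29 for flavonoids, -0.15 for light harvesting, -0.30 for chlorophyll synthesis, 0.37 for jasmonate, 0.47 for dehydration, 0.21 for the clock and -0.11 for cyclophilins. In serat2;1 they were -0.88 for heat shock, -0.55 for flavonoids, -0.11 for light harvesting, -0.25 for chlorophyll synthesis, -0.20 for glucosinolates, 0.19 for the clock, 0.55 for dark inducible genes and 0.21 for shade markers.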

How the results depend on the processing

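The fit without the arrays that stood apart, the lists without targeted genes and the shared calls with WT arrays split were chosen after seeing the data. Cyclic loess normalization, the replicate block and leaving out genes near the targeted loci kept the count of called genes of every comparison within 1.5 times, while with the block 5 and not 3 genes were called higher in all 4 mutants in NL. Quantile normalization could test nothing, as the deposited values were already so normalized and moved by at most 0.00188. Counts moved over 1.5 times as follows, with no cause tested. With an intensity trend, 30 genes were called for cyp20-3 in NL and 367 for oastlB in HL. With only the arrays compared, which leaves fewer arrays to estimate the spread, the light responses of 2cysprx, oastlB and serat2;1 held 873, 2532 and 1407 genes. For the mutants in the order 2cysprx, cyp20-3, oastlB and serat2;1, that fit called 618, 2, 2 and 0 in NL (limma, with 3567 at an unadjusted p under 0.05 for serat2;1), 151, 390, 31 and 2 in HL, and 1006, 142, 140 and 184 for the difference in light response. Among the brighter genes alone, where fewer are tested, 41, 1579 and 1051 were called in NL for cyp20-3, oastlB and serat2;1 and 1342 for the oastlB difference in response. Array weights gave 8 for cyp20-3 in NL and 1036 and 1047 for 2cysprx and cyp20-3 in HL. Without the arrays that stood apart, the count was 2964 for the oastlB light response, 1649 and 6 for 2cysprx and cyp20-3 in NL, 20 for oastlB in HL, and 1042 and 163 for the 2cysprx and oastlB differences in response.

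Leaving out 1 array moved 52 counts beyond 1.5 times and left 116 within it. The counts ranged from 4556 to 5137 for the WT light response and, for 2cysprx, cyp20-3, oastlB and serat2;1 in turn, 1890 to 2116, 4068 to 4453, 3732 to 4168 and 2496 to 2949 for light, 1954 to 2875, 3 to 19, 420 to 987 and 335 to 634 in NL, 300 to 555, 409 to 544, 69 to 320 and 76 to 336 in HL, and 1267 to 1835, 119 to 204, 414 to 958 and 328 to 766 for the difference in response. SERAT2;1 in serat2;1 in NL, which was not called, turned to -0.0160, -0.0391 and -0.0756 without serat2;1 NL replicate 2, serat2;1 NL replicate 4 and WT NL replicate 3. Of 440 results on named genes, 96 lost their call without 1 array, and 16 with array weights, 66 without the arrays that stood apart, 145 with only the compared arrays, 6 with cyclic loess and 1 with the intensity trend.

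Correlations across genes moved with the choice of genes or WT arrays. In the brighter genes the light responses of 2cysprx, cyp20-3, oastlB and serat2;1 correlated with that of WT at 0.515, 0.783, 0.689 and 0.658, and the differences from WT at 0.760 for 2cysprx and oastlB and 0.708 for 2cysprx and serat2;1 in NL and 0.340 for 2cysprx and oastlB, 0.161 for cyp20-3 and oastlB and 0.549 for cyp20-3 and serat2;1 in HL. The cyp20-3 light correlation ranged from 0.634 to 0.658 when 1 array was left out. With WT arrays split, which removes the shared values, r was 0.109 for 2cysprx and cyp20-3, 0.278 for 2cysprx and oastlB, 0.246 for 2cysprx and serat2;1, 0.0979 for cyp20-3 and oastlB, 0.0991 for cyp20-3 and serat2;1 and 0.202 for oastlB and serat2;1 in NL, and 0.0964, 0.184, 0.249, 0.0370, 0.208 and 0.307 in HL. Of 391 list results, 87 calls ended with an estimated correlation, fry ended 21 and added 33, and leaving out the arrays that stood apart ended 6 and added 6. In the brighter genes 19 calls ended and 5 were added. Of 16 list results for a list that holds the line's targeted gene, leaving that gene out ended 2 calls (sulfate assimilation for oastlB in NL, cyclophilins for cyp20-3 in HL) and added 2, antioxidant enzymes for 2cysprx in NL (median 0.07, adjusted p = 0.0461) and cyclophilins for the cyp20-3 difference in response (-0.08, adjusted p = 0.0379), neither called with an estimated correlation (adjusted p = 0.12 and 0.0808).

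Groups share replicate numbers, which were not taken to pair the arrays, since r across genes of their deviations was above 0.1 in 3 of 180 pairs with the same number and not in all (-0.129 to 0.122). The mean r was 0.0141 for the same and -0.00460 for different numbers, and 19 of 40 arrays lay closest to their own number, where chance gives about 10, a hint from the data that arrays with the same number share a little. With the replicate block 5692 genes were called for the WT light response and 15 for cyp20-3 in NL. The block ended 4 calls of named genes, those of PORC in the 2cysprx light response (adjusted p = 0.0503), RL1 in cyp20-3 in NL (0.0524), PDF1.2 in serat2;1 in HL (0.0534) and HSP101 in the serat2;1 difference in response (0.0505), and added 4 list calls in 2cysprx in HL. Signal over background is unknown, so what dim genes limit was not measured.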

Other observations

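The tests of calls near the targeted locus in cyp20-3 and of the light axis were chosen only after the result was seen, as were the genes of this part. AT3G01345 read 4.03, 7.72, 3.72 and 6.60 on the 4 WT arrays in NL and 6.98 to 8.15 in WT in HL, against 2.58 to 4.91 on the mutant arrays, so that WT itself was split in NL. AT4G05370 read 4.56 to 5.60 on all 8 arrays of 2cysprx and 1.60 to 3.15 on all others. HSFA2 in WT in HL read 6.18, 4.3, 7.25 and 8.16.

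A hypothesis is that variants linked to each insertion change genes near the targeted locus. Calls in NL numbered 50 of 433 genes near the loci in 2cysprx (exact Fisher p = 0.335 against other genes), 1 of 225 in cyp20-3 (exact p = 0.0929), 9 of 227 in oastlB (exact p = 0.582) and 8 of 201 in serat2;1 (exact p = 0.159). None of these passed the threshold, and the intervals of the odds ratios are too wide to exclude such variants.

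Another hypothesis is that 2cysprx in normal light lies toward the high light state. Across genes, its difference from WT in NL correlated with the mean light response of the other 3 mutants, with which it shares no array, at r = 0.150 (-0.191 in HL), below the 0.3 set for the hypothesis and above the 0.1 set against it, so the question stays open.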
